A study of Mus musculus with 30 samples.

How the data were processed

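RNA was measured in 30 libraries, quadriceps and whole spinal cord of 15 male mice aged 4 months, with 3 libraries in each of 10 groups. Per the labels' protocols, both tissues came from the same animal, RNA was purified from snap-frozen tissue, and polyA RNA libraries (NEBNext Ultra RNA kit) were read single-end at 61 bases on an Illumina HiSeq2500. Treated mice were injected intravenously as neonates with an AAV9 vector for human GAA under a liver-muscle promoter. Column names put the B6129 samples in series A and the samples of the mixed B6129;DBA2/J background in series B, so background and series cannot be told apart.

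Per the submitters' processing notes, reads were handled with cutadapt, RSEM, edgeR and limma on GRCm38, with no versions, parameters or gene filter given. The deposited table gives a linear signal for 17420 genes, a normalized count. Every deposited signal equals the read count plus 0.5, divided by a scaled library size: 100% of the values gave whole reads within 0.001. The table is therefore linear, and a gene without reads stands above 0. Recovered reads came to 1.69e+07 to 3.71e+07 per quadriceps library (median 2.67e+07) and 1.92e+07 to 3.42e+07 per cord library (median 2.22e+07). A single read is worth 0.0329 to 0.072 in quadriceps and 0.0179 to 0.0369 in cord, and 3 reads 0.0987 to 0.216 and 0.0536 to 0.111, so levels below these rest on very few reads. Mitochondrial genes took 6.99% to 7.7% of cord reads in series A and 13.2% to 17.1% in series B, and 13.2% to 21.1% and 14.7% to 18.3% in quadriceps.

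Columns were joined to samples by the names in the descriptions. For the treated cord samples the descriptions name the same column for 2 samples and an unknown column for the other, so these were joined by the animal number in the title; either joining leaves the group the same. Of the gene identifiers, 17388 (99.8%) were found in the GENCODE vM21 annotation used for positions and gene types.

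Values were analysed as log2(signal + 0.5) with R 4.3.3. Genes with a signal of at least 1 in at least 3 libraries of the tissue were kept: 14113 in quadriceps, 15838 in cord and 13187 in both. For each tissue 1 linear model with the 5 groups was fitted with limma 3.58.1 to all 15 libraries, and contrasts were tested by moderated tests (eBayes with an intensity trend). The contrasts were KO against WT on each background, treated against untreated KO, treated KO against WT, the difference of the KO effect between backgrounds, and WT against WT of the other background. The difference of the KO effect between tissues was tested in a fit of all 30 libraries. Genes are called changed at an adjusted p (Benjamini-Hochberg) under 0.05; the share of tested genes whose 3 and 3 libraries do not overlap was also counted, where chance gives 10%. Fold changes are differences of mean log2 values.

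In each comparison the text names Gaa and Ltbp4, genes from the 10 largest changes in each direction among called genes whose libraries do not overlap, and genes from the 4 called members with the smallest adjusted p in each list that was called or had at least 2 called members. A set of 37 gene lists (627 entries) was fixed before any values were seen, with markers of other cell types that a dissected sample could hold, and lists with at least 5 measured genes were tested with camera (preset inter-gene correlation 0.01, adjusted over all lists of the comparison). Each was also tested with an estimated correlation, with fry and after quantile normalization. Member counts are given over all genes and with the adjustment made over the list alone.

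The genes called between KO and WT on B6129 were scored in each library of the mixed background (mean log2 of the genes up minus that of the genes down) and compared by exact permutation, where the smallest p with 3 and 3 libraries is 0.1. Genes reversed by treatment, and genes still changed against WT, were counted by direction. Since those pairs of contrasts share 3 libraries, they were set beside the product of the list sizes over the number of genes and beside 20 simulations in which treated libraries equal the untreated KO or WT libraries.

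The pipeline was tested on simulated data, with reads drawn at the dispersion of each gene and 200 genes changed in the treated libraries in each of 3 runs. In cord it found 56% of 1.5-fold and 78.7% of 2-fold changes, with 25 of 429 calls (5.83%) on unchanged genes; in quadriceps 29.7% and 65.7%, with 24 of 310 (7.74%). A planted list was found in 3 of 3 runs and 0 of 60 random lists were called. Genes were drawn independently of each other, so this does not test lists whose genes vary together. Tissues of the same animal were more alike in their deviations from group means than those of group mates in 15 of 15 animals (correlation 0.109 to 0.354). For the 3 treated animals this pairing rests on the joining by animal number.

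Alternatives fixed in advance were a pseudocount and a filter level 4 times larger, no filter, quantile normalization, a median shift, eBayes without trend and robust eBayes, array weights, a fit of the compared groups alone, each library left out in turn, and animal as a fixed or random block for the tissue difference. Added after the values were seen were edgeR 4.0.16 (quasi-likelihood on the recovered reads), a fit without the 2 cord libraries with most muscle and nerve RNA, removal of a trend with transcript length and GC content in cord, a fit without mitochondrial genes and with a median shift, and counts without genes on chromosome 4 and near Gaa. Gene lists and the filter were not changed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.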

Results

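Quadriceps and whole spinal cord came from 15 male mice aged 4 months, in 5 groups of 3. The groups were wild type (WT) and Gaa knockout (KO) mice on a B6129 background, and WT, KO and treated KO mice on a mixed B6129;DBA2/J background. Treated KO mice had received a neonatal intravenous AAV9 vector carrying human GAA. Levels are mean ± SD of 3 libraries in the deposited signal, differences are log2 ± SE, and adjusted p-values come from limma. The table holds mouse genes, so Gaa below stands for the mouse gene. Whether any reads of the human transgene were counted under it was not checked.

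Gaa encodes acid alpha-glucosidase, the lysosomal enzyme that degrades glycogen, and its transcript was lower in every KO group. In quadriceps it stood at 15.8 ± 0.426 in KO and 275 ± 29 in WT on B6129 (-4.07 ± 0.15, n = 3 each, adjusted p = 1.63e-09), and at 14.9 ± 2.91 and 213 ± 42.7 on the mixed background (-3.79 ± 0.15, adjusted p = 4.52e-09). In cord the levels were 16.8 ± 1.02 and 225 ± 9.4 on B6129 (-3.70 ± 0.09, adjusted p = 3.75e-12), and 12.1 ± 1.41 and 138 ± 6.4 on the mixed background (-3.47 ± 0.09, adjusted p = 9.51e-12). Treated KO mice had 18 ± 0.913 in quadriceps and 9.21 ± 1.1 in cord, differences from untreated KO of 0.28 ± 0.15 (adjusted p = 0.158) and -0.37 ± 0.09 (adjusted p = 0.141). Ltbp4 encodes a latent TGF-beta binding protein, and its DBA/2J allele is a known modifier of muscular dystrophy in mice. In quadriceps Ltbp4 fell in KO on B6129 (42 ± 1.36 against 70.7 ± 6.47, -0.74 ± 0.19, adjusted p = 0.00692) and on the mixed background (34.5 ± 6.85 against 72.2 ± 14.6, -1.05 ± 0.19, adjusted p = 0.000612). It rose with treatment to 113 ± 29.8 (1.68 ± 0.19 over untreated KO, adjusted p = 1.14e-05). In cord Ltbp4 was 27.5 ± 1.61 in KO and 28.4 ± 2.48 in WT on B6129 (-0.05 ± 0.11, adjusted p = 0.937) and rose in KO on the mixed background (17.2 ± 3.09 against 11.9 ± 1.56, 0.50 ± 0.11, adjusted p = 0.0118), with 17.1 ± 0.133 in treated KO mice (0.01 ± 0.11 from untreated KO, adjusted p = 0.986).

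**Figure D1:**
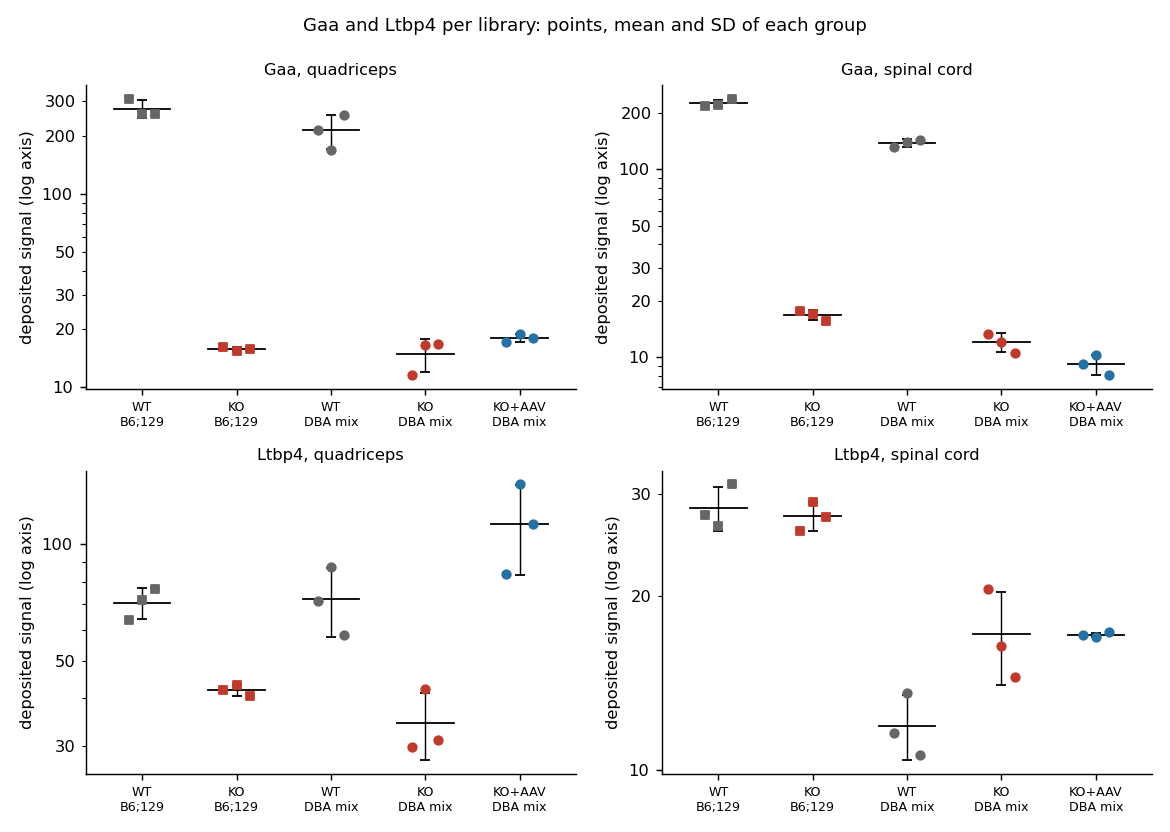
Deposited signal of Gaa and Ltbp4 (log axis) in each library, by group and tissue, with group mean and SD (n = 3). Mean Gaa is 138 to 275 in the 4 WT groups and 9.21 to 18 in the 6 KO groups, treated or not.

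In KO quadriceps on B6129, many genes of lysosomes, embryonic muscle, denervation and macrophages were higher, and many of glycogen handling were lower. As lists, only lysosomal genes stayed called with an estimated correlation. Mt3, a metallothionein, went from 1.33 ± 0.0895 to 219 ± 23.2 (6.90 ± 0.36, n = 3 each, adjusted p = 5.13e-08). Lgals3, the lysosome damage sensor and macrophage lectin galectin-3, went from 2.7 ± 0.752 to 132 ± 29.3 (5.38 ± 0.33, adjusted p = 2.11e-07). Mstn, which encodes the muscle growth inhibitor myostatin, fell from 106 ± 20.9 to 8.54 ± 2.09 (-3.57 ± 0.20, adjusted p = 9.01e-08), and Aqp4, the water channel of fast fibres and astrocytes, fell from 51 ± 8.21 to 3.74 ± 0.371 (-3.60 ± 0.30, adjusted p = 1.73e-06).

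Lysosomal genes rose in this comparison: 21 of 30 measured members rose and 0 fell over all genes (23 and 0 adjusted over the list alone). The lysosome list gave adjusted p = 2.88e-10, and adjusted p = 0.0442 with an estimated correlation. Hexa, a subunit of beta-hexosaminidase, rose from 53.1 ± 2.12 to 163 ± 9.32 (1.61 ± 0.11), and Lamp1, an abundant lysosomal membrane protein, by 0.65 ± 0.06. Vacuolar ATPase subunits, which acidify lysosomes, rose with 11 of 16 up and 0 down over all genes as over the list alone (Atp6v1a 0.98 ± 0.11, Atp6ap2 1.15 ± 0.13). The vacuolar ATPase list gave adjusted p = 2.27e-05, and adjusted p = 0.142 with an estimated correlation. Glycogen genes fell, 12 of 21 down and 2 up by either adjustment (adjusted p = 0.00155, and adjusted p = 0.208 with an estimated correlation). Phkb, a subunit of phosphorylase kinase, fell from 776 ± 41.4 to 381 ± 16.9 (-1.03 ± 0.08).

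Muscle regeneration genes rose, 15 of 18 by either adjustment and none down (adjusted p = 3.32e-10, and adjusted p = 0.0666 with an estimated correlation). They include the embryonic isoforms Myl4 (67.1 ± 22.7 against 4.86 ± 0.86, 3.62 ± 0.23) and Myh3 (3.77 ± 0.26), and Mymk, which encodes the fusion protein myomaker (4.00 ± 0.27). Of 20 denervation and atrophy genes, 12 rose and 2 fell by either adjustment (adjusted p = 6.02e-06, and adjusted p = 0.114 with an estimated correlation), among them the acetylcholine receptor subunits Chrna1 (67.2 ± 8.49 against 15.7 ± 1.44, 2.06 ± 0.13) and Chrnd (3.52 ± 0.24). Fast fibre genes fell, 6 of 14 over all genes and 8 over the list alone (Myh4 -0.73 ± 0.17, Actn3 -0.72 ± 0.15; adjusted p = 0.0242, and adjusted p = 0.563 with an estimated correlation), but under quantile normalization the list pointed up (adjusted p = 0.289). Macrophage genes rose, 19 of 20 by either adjustment (Mpeg1 3.36 ± 0.26; adjusted p = 9.73e-10, and adjusted p = 0.215 with an estimated correlation), as did all 7 MHC class II genes (Cd74 2.37 ± 0.23). The MHC class II list gave adjusted p = 1.25e-06, and adjusted p = 0.19 with an estimated correlation. Extracellular matrix genes rose, 17 of 25 over all genes and 18 over the list alone (Col1a2 1.24 ± 0.20). The extracellular matrix list gave adjusted p = 9.12e-07, and adjusted p = 0.371 with an estimated correlation. Endothelial genes fell, 7 of 10 over all genes and 8 over the list alone (Flt1 -1.05 ± 0.24, Cdh5 -0.73 ± 0.15). The endothelial list gave adjusted p = 0.00346, and adjusted p = 0.371 with an estimated correlation.

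Across all genes, 5046 of 14113 were called in this comparison, 2359 up and 2687 down, 1182 of them over 2-fold. The 3 KO and 3 WT libraries did not overlap at 53.9% of the tested genes, against 10% by chance. Of 34 lists, 20 were called with the preset correlation, 1 with an estimated correlation and 15 after quantile normalization.

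**Figure D2:**
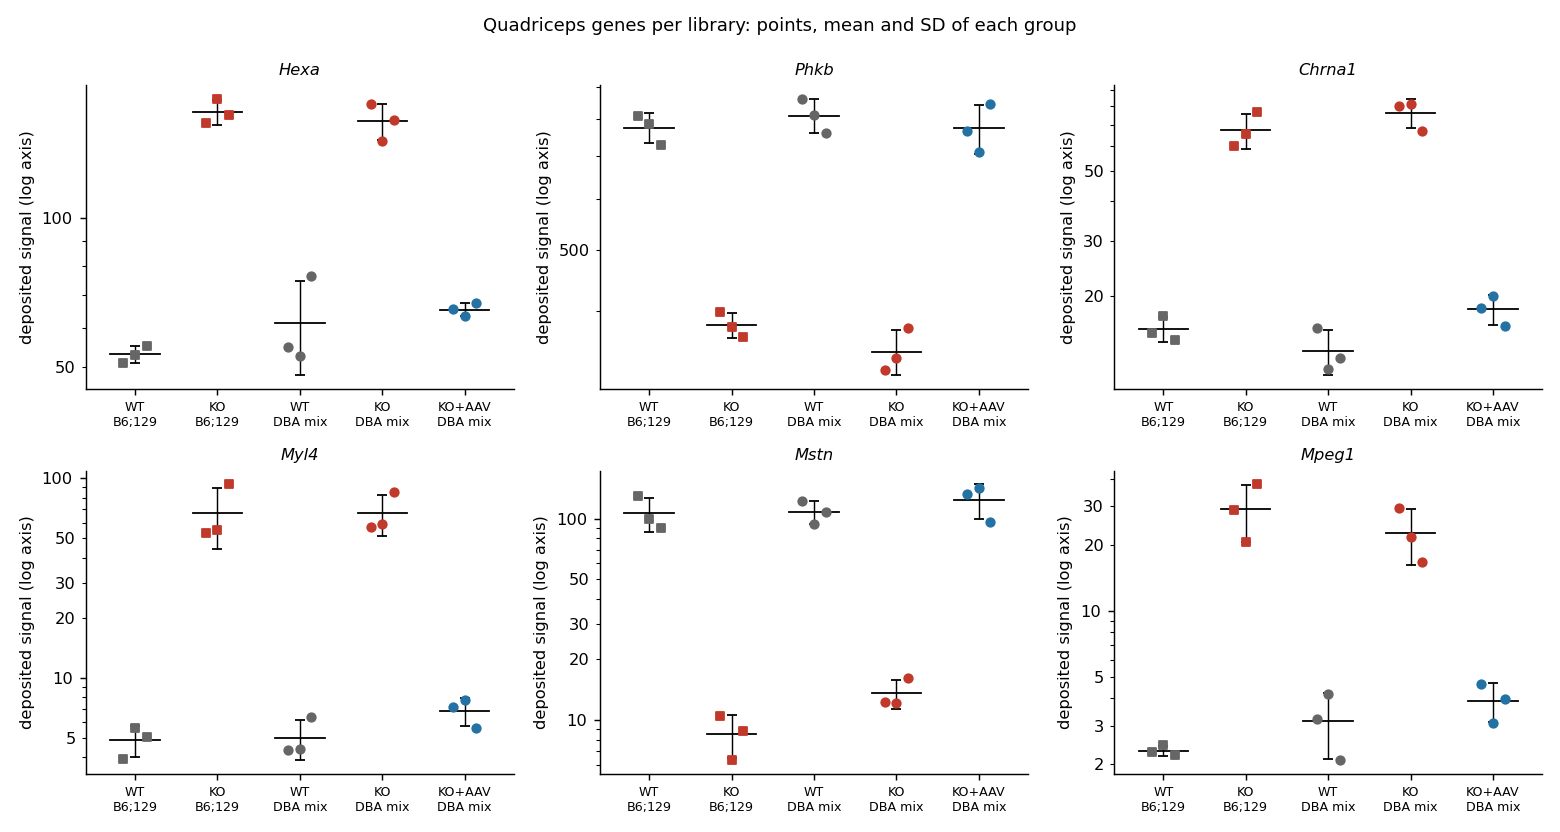
Deposited signal (log axis) of 6 quadriceps genes in each library, by group, with group mean and SD (n = 3). Chrna1 averages 67.2 and 76.2 in the untreated KO groups and 18.1 in treated KO mice, against 15.7 and 13.4 in the WT groups.

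KO quadriceps on the mixed background showed a largely shared set of changes. Mt3 went from 1.49 ± 1.12 to 298 ± 22.6 (7.38 ± 0.36, n = 3 each, adjusted p = 3.89e-08), Hexa from 61.4 ± 13.1 to 157 ± 13.3 (1.36 ± 0.11), Phkb from 811 ± 49.7 to 346 ± 27.7 (-1.23 ± 0.08), and Mstn from 108 ± 14.4 to 13.6 ± 2.24 (-2.96 ± 0.20). Sln, which encodes the calcium pump regulator sarcolipin, rose from 4.02 ± 1.63 to 66.5 ± 16.6 (3.92 ± 0.30, adjusted p = 8.25e-07). Pygm, the muscle glycogen phosphorylase, fell from 10900 ± 1390 to 4950 ± 641 (-1.14 ± 0.12, adjusted p = 1.22e-05).

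On this background 20 of 30 lysosomal genes rose and 0 fell by either adjustment (adjusted p = 6.03e-08, and adjusted p = 0.102 with an estimated correlation). Of 16 vacuolar ATPase genes 11 rose and 0 fell over all genes, 13 and 1 over the list alone (adjusted p = 2.25e-05, and adjusted p = 0.204 with an estimated correlation). Of 21 glycogen genes 11 fell and 1 rose by either adjustment (adjusted p = 0.0115, and adjusted p = 0.404 with an estimated correlation). Regeneration genes rose, 12 of 18 over all genes and 13 over the list alone (Myl4 3.61 ± 0.23). The regeneration list gave adjusted p = 7.98e-07, and adjusted p = 0.204 with an estimated correlation. Denervation genes had 10 up and 2 down of 20, 12 and 2 over the list alone (Chrna1 2.47 ± 0.13, Chrnd 3.55 ± 0.24). The denervation list gave adjusted p = 0.000211, and adjusted p = 0.204 with an estimated correlation. Slow fibre genes rose, 7 of 12 over all genes and 9 over the list alone (Casq2 17.5 ± 2.68 to 92.7 ± 18.3, 2.37 ± 0.17; Tnni1 1.72 ± 0.44). The slow fibre list gave adjusted p = 0.000751, and adjusted p = 0.494 with an estimated correlation.

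Fast fibre genes fell, 7 of 14 by either adjustment (Actn3 -1.10 ± 0.15, Myh4 -1.02 ± 0.17; adjusted p = 0.0297, and adjusted p = 0.58 with an estimated correlation), while under quantile normalization the list pointed up (adjusted p = 0.915). Macrophage genes rose, 17 of 20 by either adjustment (Mpeg1 2.67 ± 0.26; adjusted p = 7.98e-07, and adjusted p = 0.404 with an estimated correlation), as did all 7 MHC class II genes (H2-Aa 2.39 ± 0.28). The MHC class II list gave adjusted p = 9.97e-06, and adjusted p = 0.246 with an estimated correlation. Interferon and MHC class I genes rose, 9 of 23 over all genes and 11 over the list alone (B2m 0.97 ± 0.18). The interferon list gave adjusted p = 0.000751, and adjusted p = 0.494 with an estimated correlation. Endothelial genes fell, 5 of 10 over all genes and 7 over the list alone (Tie1 -0.78 ± 0.15, Cdh5 -0.74 ± 0.15). The endothelial list gave adjusted p = 0.0165, and adjusted p = 0.494 with an estimated correlation. Of 10 Schwann cell genes, a marker of nerve in the sample, 6 rose by either adjustment (median 0.502; adjusted p = 0.0114, and adjusted p = 0.494 with an estimated correlation).

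In total 5562 of 14113 genes were called, 2414 up and 3148 down, 1165 over 2-fold, and libraries did not overlap at 46.4% of the tested genes against 10% by chance. Up in both backgrounds were 1620 genes against 404 expected of independent lists, down in both 2015 against 599, and 19 went opposite ways (r = 0.742 over all genes). A direct test of the difference between the 2 knockout effects called 40 genes, 14 with a higher and 26 with a lower effect on the mixed background. Among them is Fosb, an immediate-early gene (-3.42 ± 0.49, adjusted p = 0.0149). Fosb stood at 0.72 to 0.756 in WT libraries on B6129 and 8.71 to 10.8 on the mixed background. KO libraries held 2.24 to 3.21 and 1.59 to 2.66, so the Fosb difference lies mainly in the WT groups. The cell cycle inhibitor Cdkn2a was also called (-2.05 ± 0.34, adjusted p = 0.0246). So was Kif24, a kinesin gene on chromosome 4 (3.09 ± 0.34, adjusted p = 0.0011). Gaa (0.29 ± 0.21, adjusted p = 0.667) and Ltbp4 (-0.31 ± 0.26, adjusted p = 0.718) were not called. That test gave 10 genes with edgeR and 11 to 116 when single libraries were left out, and 29 of the 40 differ by over 2-fold.

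**Figure D3:**
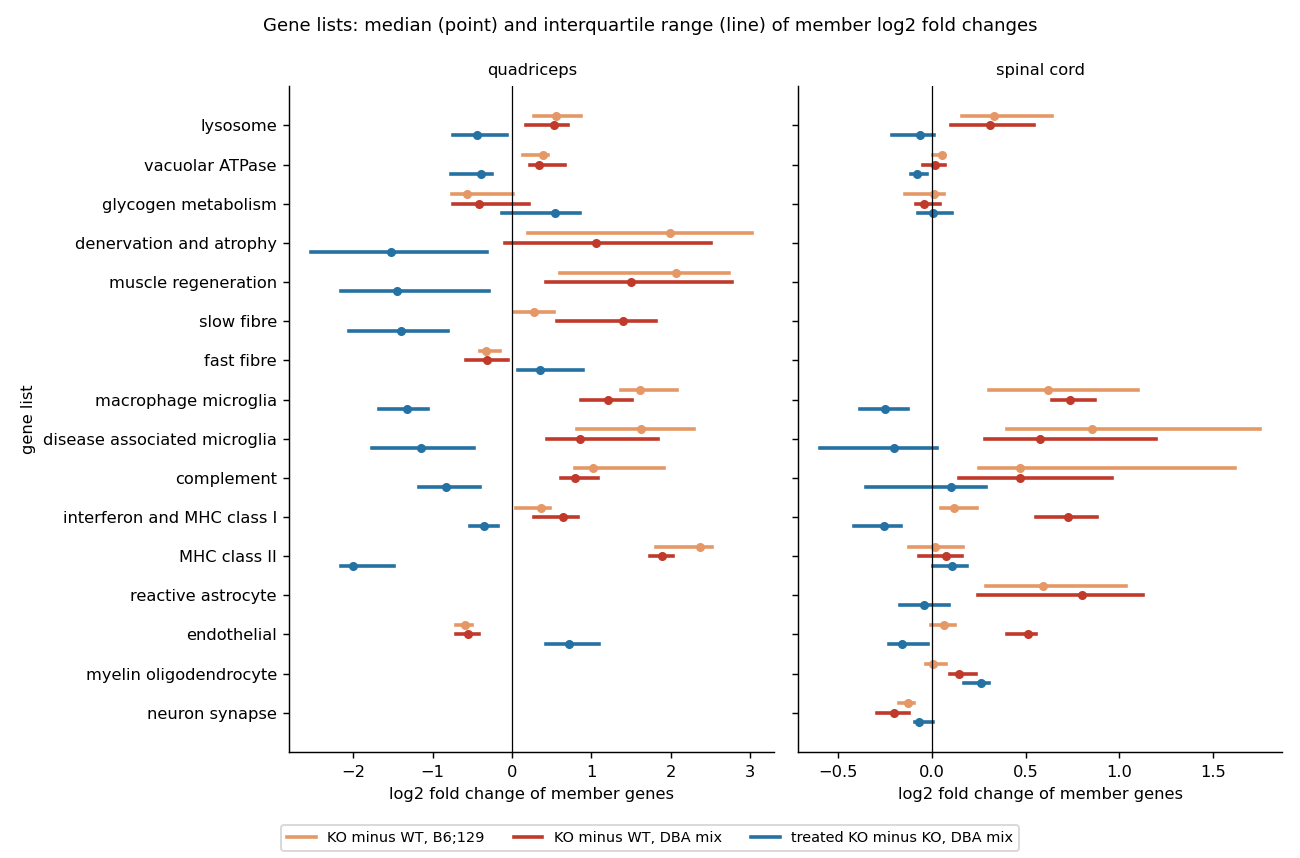
Median (point) and interquartile range (line) of the log2 fold changes of member genes, per gene list, for KO minus WT on each background and treated minus untreated KO, in quadriceps (left) and cord (right); muscle lists are drawn for quadriceps and neural lists for cord. The macrophage list has medians of 1.62, 1.2 and -1.33 in quadriceps and 0.62, 0.735 and -0.251 in cord.

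With treatment, quadriceps gene levels moved back towards WT. Mt3 fell from 298 ± 22.6 in untreated to 2.13 ± 1.09 in treated KO mice (-6.93 ± 0.36, n = 3 each, adjusted p = 5.41e-08), Sln from 66.5 ± 16.6 to 2 ± 0.269 (-4.71 ± 0.30, adjusted p = 2.32e-07) and Hexa from 157 ± 13.3 to 65.4 ± 1.97 (-1.25 ± 0.11, adjusted p = 2.65e-06). Mstn rose from 13.6 ± 2.24 to 123 ± 24.3 (3.13 ± 0.20, adjusted p = 2.32e-07), Phkb from 346 ± 27.7 to 775 ± 68.2 (1.16 ± 0.08, adjusted p = 5.43e-07) and Pygm by 1.41 ± 0.12 (adjusted p = 1.85e-06).

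Of 30 lysosomal genes 16 fell and 1 rose with treatment, 17 and 1 over the list alone (Lamp1 -0.67 ± 0.06). The lysosome list gave adjusted p = 3.73e-06, and adjusted p = 0.161 with an estimated correlation. Vacuolar ATPase genes had 12 down and 1 up of 16, 13 and 1 over the list alone (Atp6v1a -1.06 ± 0.11). The vacuolar ATPase list gave adjusted p = 3.73e-06, and adjusted p = 0.161 with an estimated correlation. Glycogen genes rose, 11 of 21 with 1 down, or 2 down over the list alone. The glycogen list gave adjusted p = 0.00561, and adjusted p = 0.311 with an estimated correlation. Regeneration genes fell, 11 of 18 over all genes and 12 over the list alone (Myl4 67.2 ± 15.7 to 6.84 ± 1.11, -3.19 ± 0.23; Myh3 -2.97 ± 0.26). The regeneration list gave adjusted p = 3.73e-06, and adjusted p = 0.161 with an estimated correlation. Denervation genes had 11 down and 3 up of 20 by either adjustment (Chrna1 76.2 ± 8.05 to 18.1 ± 2, -2.04 ± 0.13). The denervation list gave adjusted p = 7.92e-05, and adjusted p = 0.161 with an estimated correlation. Slow fibre genes fell, 8 of 12 by either adjustment (Casq2 -1.44 ± 0.17, Tnni1 -2.52 ± 0.44). The slow fibre list gave adjusted p = 0.000774, and adjusted p = 0.494 with an estimated correlation. Fast fibre genes rose, 7 of 14 by either adjustment (Myh4 1.31 ± 0.17, Actn3 1.14 ± 0.15; adjusted p = 0.0243, and adjusted p = 0.615 with an estimated correlation), but pointed down under quantile normalization (adjusted p = 0.849).

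Macrophage genes fell with treatment, 17 of 20 over all genes and 19 over the list alone (Mpeg1 22.7 ± 6.48 to 3.9 ± 0.778, -2.38 ± 0.26). The macrophage list gave adjusted p = 3.69e-07, and adjusted p = 0.336 with an estimated correlation. All 7 MHC class II genes fell (H2-Aa -2.65 ± 0.28; adjusted p = 1.64e-05, and adjusted p = 0.285 with an estimated correlation). Endothelial genes rose, 6 of 10 by either adjustment (Cdh5 1.26 ± 0.15, Tie1 1.18 ± 0.15; adjusted p = 0.00747, and adjusted p = 0.494 with an estimated correlation). Blood cell genes had a median of -1.61 (0 of 6 called, adjusted p = 0.174).

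Treatment changed 5736 of 14113 genes in quadriceps, 3325 up and 2411 down, 1239 over 2-fold, and libraries did not overlap at 49.4% of the tested genes against 10% by chance. Of the 5562 genes that the knockout changed, 4059 (73%) changed in the opposite direction with treatment: 1676 were up and then down against 412 expected, 2383 down and then up against 742 expected, and 11 moved the same way. The untreated KO libraries enter both differences. In 20 simulations with treated libraries drawn equal to untreated ones, a median of 0 genes reversed. With no treatment effect almost no gene can be called, so that 0 does not measure what the shared libraries add. Opposite signs made up 57.7% of the knockout calls in the simulations against 97.1% observed. The covariance of the 2 differences was -0.355 against -0.0273 in simulations with no effect, so a small part of the excess may come from the shared libraries.

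Treated KO and WT quadriceps still differed at some genes. Gaa stayed low (18 ± 0.913 against 213 ± 42.7, -3.51 ± 0.15, n = 3 each, adjusted p = 1.47e-08) and Ltbp4 stood at 113 ± 29.8 against 72.2 ± 14.6 (0.63 ± 0.19, adjusted p = 0.0765). Kif24 (7.77 ± 1.24 against 1.52 ± 0.722, 2.08 ± 0.24, adjusted p = 0.000826) was higher. So were the anion transporter Slc26a11 (1.67 ± 0.15, adjusted p = 8.1e-05) and the collagen gene Col1a2 (270 ± 33.1 against 138 ± 7.63, 0.96 ± 0.20, adjusted p = 0.0227). Kif24 lies on chromosome 4 and Slc26a11 near Gaa on chromosome 11, regions weighed below. In untreated KO quadriceps Kif24 differed from WT by 2.33 on the mixed background and -0.76 on B6129, and Slc26a11 by 1.77 and 0.375. Gpr75, a receptor gene (-1.67 ± 0.22, adjusted p = 0.00331), Ech1 of fatty acid oxidation (-0.54 ± 0.11, adjusted p = 0.0255) and Ndufb8 of respiratory complex I (-0.31 ± 0.08, adjusted p = 0.0437) were lower. Of the lists, 4 were called and 0 with an estimated correlation (adjusted p = 0.99 each): respiratory chain (median -0.148, 1 of 25 down, adjusted p = 0.00288), fatty acid oxidation (-0.254, 1 of 20 down, adjusted p = 0.000133), extracellular matrix (0.349, 1 of 25 up, adjusted p = 0.00288) and Schwann cell genes (0.404, 1 of 10 up, adjusted p = 0.0409). Blood cell genes had a median of -1.65 (0 of 6 called, adjusted p = 0.0674). Called genes numbered 421, 273 up and 148 down, or 194 up and 196 down after a median shift. They were 124 to 448 with single libraries left out and 17 when the fit held the 2 groups alone.

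Of the knockout calls in quadriceps, 140 (2.52%) were still called in the same direction against WT, 82 up against 46.7 expected and 58 down against 33 expected. The same WT libraries enter both differences. Simulated treated libraries equal to WT gave a median of 0 such genes and 1 at most. With no difference from WT drawn, almost no gene can be called, so these counts do not measure what the shared libraries add. The covariance was 0.0864 against 0.0273 simulated, so part of the excess may come from the shared libraries. A median of 7.49% of the knockout change was left. The KO and WT libraries that chose these genes also enter that share, and no simulated share stands beside it. Another 88 knockout calls were called against WT in the direction opposite to the knockout change, 15 below WT against 25.3 expected and 73 above WT against 60.9 expected, and 193 genes differed that the knockout had not changed.

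In KO cord on B6129, microglial, lysosomal and astrocyte genes were higher. Cst7, a cystatin gene of activated microglia, went from 0.143 ± 0.0403 to 3.82 ± 0.406 (2.75 ± 0.28, n = 3 each, adjusted p = 7.52e-05). Cd68, a lysosomal protein of phagocytes, rose from 2.89 ± 0.285 to 10.9 ± 1.16 (1.75 ± 0.11, adjusted p = 6.86e-07) and C1qa, a complement component, from 19.9 ± 2.15 to 62.2 ± 2.68 (1.62 ± 0.12, adjusted p = 4.16e-06). Gfap, the intermediate filament of astrocytes, rose from 928 ± 119 to 1880 ± 220 (1.02 ± 0.13, adjusted p = 0.000971).

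Of 21 genes of disease-associated microglia, 12 rose and 0 fell over all genes and 17 rose over the list alone (Trem2 5.19 ± 0.394 to 17.3 ± 0.404, 1.65 ± 0.14; Lgals3 2.35 ± 0.21; adjusted p = 5.36e-39, and adjusted p = 0.00202 with an estimated correlation). General macrophage and microglia genes rose, 10 of 22 over all genes and 16 over the list alone (Tyrobp 1.79 ± 0.14, Mpeg1 1.70 ± 0.19). The macrophage list gave adjusted p = 9.77e-31, and adjusted p = 0.00342 with an estimated correlation. Lysosomal genes rose, 14 of 30 with 0 down, or 22 with 1 down over the list alone (Ctsd 254 ± 8.37 to 515 ± 18.7, 1.02 ± 0.08; Grn 0.86 ± 0.07). The lysosome list gave adjusted p = 7.24e-36, and adjusted p = 0.00342 with an estimated correlation. Complement genes rose, 6 of 12 by either adjustment (C4b 1.86 ± 0.18; adjusted p = 1.09e-16, and adjusted p = 0.00342 with an estimated correlation). Reactive astrocyte genes rose, 8 of 20 and 13 over the list alone (Cd109 1.29 ± 0.17, Hspb1 0.56 ± 0.07). The reactive astrocyte list gave adjusted p = 7.79e-21, and adjusted p = 0.00342 with an estimated correlation. No vacuolar ATPase gene was called (adjusted p = 0.111 for the list), and the glycogen list gave adjusted p = 0.971.

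Blood cell genes, a marker of blood left in the tissue, had a median of 0.765 with 0 of 8 called (adjusted p = 0.00566, and adjusted p = 0.761 with an estimated correlation), and Hbb-bs ran from 38.7 to 614 across the cord libraries. Skeletal muscle genes had a median of -1.01 (0 of 12 called, adjusted p = 0.299) and Schwann cell genes of 0.435 (0 of 12 called, adjusted p = 0.214). In all 183 of 15838 cord genes were called on B6129, 158 up and 25 down, 57 over 2-fold, with no overlap of libraries at 23.9% of the tested genes against 10% by chance. The number was 101 to 145 with single libraries left out and 654 with array weights (424 up and 230 down).

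In KO cord on the mixed background many glial genes were again higher, together with interferon and MHC class I genes, and some neuronal genes were lower. As lists, 0 stayed called with an estimated correlation. Gfap rose from 1080 ± 154 to 2840 ± 130 (1.40 ± 0.13, n = 3 each, adjusted p = 2.97e-05), C1qa from 29.5 ± 3.02 to 78.3 ± 9.11 (1.39 ± 0.12, adjusted p = 2.19e-05) and H2-D1, an MHC class I gene, from 53.1 ± 5.85 to 94.9 ± 10.3 (0.83 ± 0.11, adjusted p = 0.000415). Gad2, an enzyme of GABA synthesis, fell from 45.1 ± 1.98 to 33.8 ± 2.21 (-0.41 ± 0.08, adjusted p = 0.00738). The nuclear noncoding RNA Neat1 fell from 224 ± 29.9 to 44 ± 7.65 (-2.34 ± 0.35, adjusted p = 0.00116). H2-D1 also lay higher in the KO cords on B6129 (70.61 to 76.69) than in the WT cords on B6129 (50.23 to 61.15).

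Macrophage and microglia genes rose, 15 of 22 over all genes and 18 over the list alone (Csf1r 39.9 ± 0.617 to 67.7 ± 0.753, 0.76 ± 0.05; adjusted p = 5.13e-16, and adjusted p = 0.0716 with an estimated correlation), and genes of disease-associated microglia rose, 12 of 21 and 16 over the list alone (Trem2 1.25 ± 0.14, Cd68 1.20 ± 0.11). The disease-associated list gave adjusted p = 3.74e-13, and adjusted p = 0.0716 with an estimated correlation. Lysosomal genes had 20 up and 1 down of 30 by either adjustment (Ctss 1.35 ± 0.13, Grn 0.90 ± 0.07). The lysosome list gave adjusted p = 3.87e-14, and adjusted p = 0.0757 with an estimated correlation. Reactive astrocyte genes rose, 12 of 20 by either adjustment (adjusted p = 6.83e-09, and adjusted p = 0.0757 with an estimated correlation). Interferon and MHC class I genes rose, 13 of 23 and 22 over the list alone (B2m 1.16 ± 0.17, Rsad2 1.02 ± 0.18). The interferon list gave adjusted p = 4.7e-13, and adjusted p = 0.116 with an estimated correlation. Endothelial genes rose, 5 of 10 and 7 over the list alone (Pecam1 0.78 ± 0.12, Flt1 0.56 ± 0.09). The endothelial list gave adjusted p = 9.23e-06, and adjusted p = 0.1 with an estimated correlation. Cholesterol synthesis genes rose, 4 of 20 over all genes and 17 over the list alone (Sqle 0.31 ± 0.06). The cholesterol list gave adjusted p = 3.42e-06, and adjusted p = 0.434 with an estimated correlation. Neuronal and synaptic genes fell, 8 of 20 and 11 over the list alone (Gad1 -0.33 ± 0.08). The neuronal list gave adjusted p = 9.88e-06, and adjusted p = 0.439 with an estimated correlation. Among markers of other tissue in the sample, blood cell genes had a median of 0.873 (0 of 8 called, adjusted p = 0.223) and skeletal muscle genes of -1.18 (0 of 12 called, adjusted p = 0.239).

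On this background 2061 of 15838 cord genes were called, 1134 up and 927 down (992 up and 1208 down after a median shift), 125 over 2-fold, with no overlap at 29.2% of the tested genes against 10% by chance. Up on both backgrounds were 128 genes against 11.3 expected, down 7 against 1.46, and 1 was opposite (r = 0.329 over all genes). The direct test of the difference between backgrounds called 83 genes, 66 with a higher effect on the mixed background, among them the basement membrane collagen Col4a2 (1.16 ± 0.15, adjusted p = 0.0029), and 17 with a lower one, among them Neat1 (-2.54 ± 0.49, adjusted p = 0.0359) and the B cell receptor Cd22 (-1.49 ± 0.28, adjusted p = 0.0274). Neither Gaa (0.24 ± 0.12, adjusted p = 0.497) nor Ltbp4 (0.54 ± 0.16, adjusted p = 0.171) was called. Array weights gave 1365 calls for the knockout on the mixed background, the 6 libraries alone 570, and the lowest count without a single library was 918. The difference between backgrounds gave 139 with array weights and 43 to 95 with single libraries left out.

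**Figure D4:**
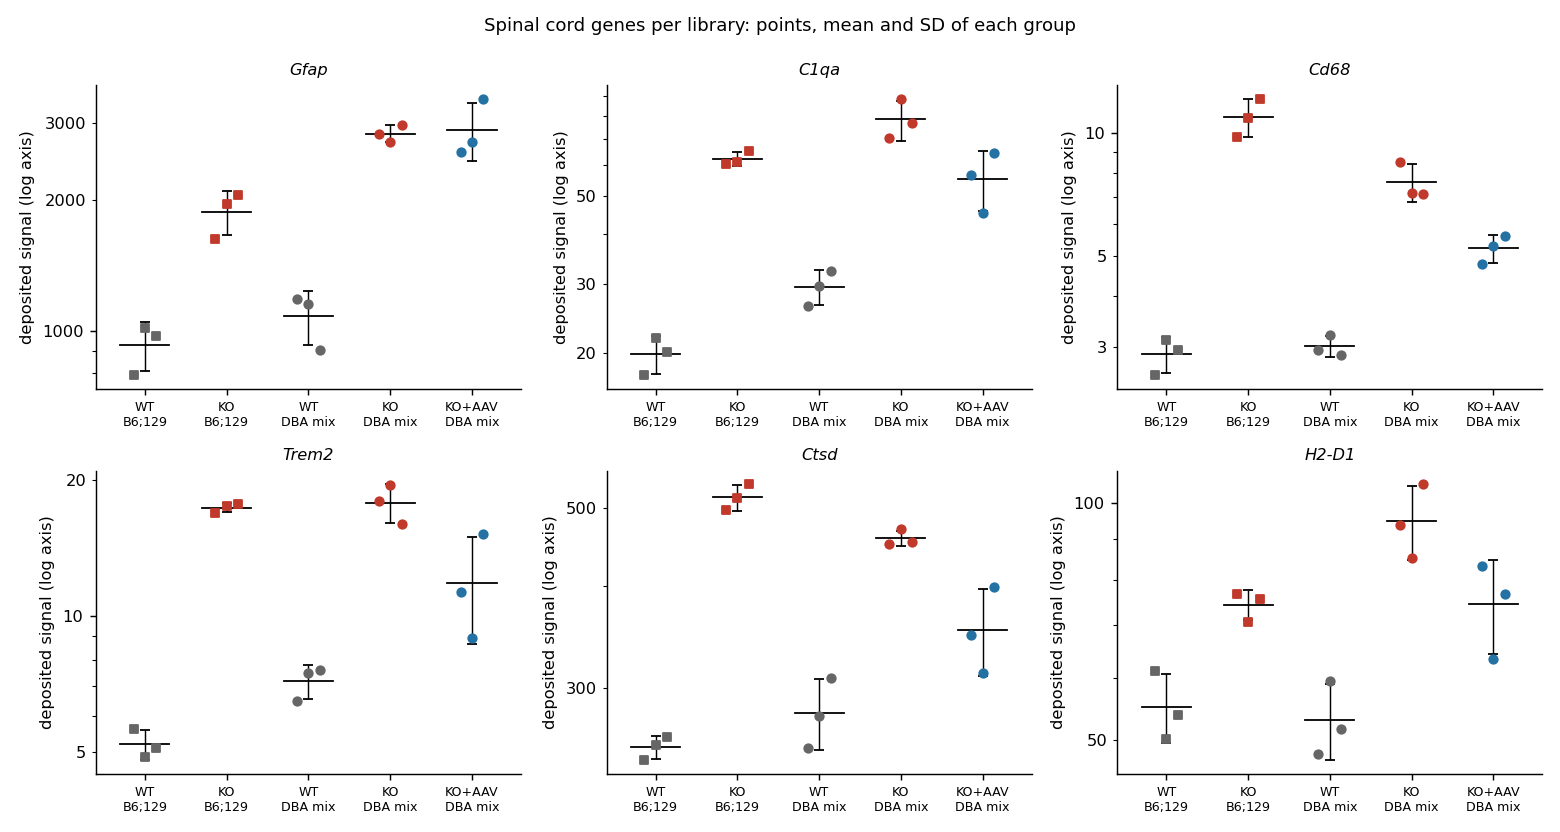
Deposited signal (log axis) of 6 spinal cord genes in each library, by group, with group mean and SD (n = 3). Gfap averages 2840 in untreated and 2900 in treated KO mice against 1080 in WT mice of the mixed background, and Cd68 averages 7.58, 5.24 and 3.02.

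In treated KO cord, many glial and lysosomal genes remained above WT, though 0 lists stayed called with an estimated correlation. Gfap stood at 2900 ± 446 against 1080 ± 154 in WT (1.42 ± 0.13, n = 3 each, adjusted p = 5.03e-05), C1qa at 55.4 ± 9.6 against 29.5 ± 3.02 (0.89 ± 0.12, adjusted p = 0.000539), Cd68 at 5.24 ± 0.408 against 3.02 ± 0.176 (0.70 ± 0.11, adjusted p = 0.00122) and Lgals3 at 8.07 ± 2.28 against 1.7 ± 0.547 (1.96 ± 0.21, adjusted p = 0.000109). Cldn11, a tight junction protein of myelin, stood at 546 ± 35.8 against 331 ± 22.5 (0.72 ± 0.08, adjusted p = 0.000159). Gaa stayed low (9.21 ± 1.1 against 138 ± 6.4, -3.84 ± 0.09, adjusted p = 2.26e-12) and Ltbp4 was higher (17.1 ± 0.133 against 11.9 ± 1.56, 0.51 ± 0.11, adjusted p = 0.00831).

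Of 30 lysosomal genes 20 were higher than in WT and 0 lower, 24 over the list alone (Scarb2 0.50 ± 0.05). The lysosome list gave adjusted p = 3.97e-11, and adjusted p = 0.109 with an estimated correlation. Macrophage and microglia genes were higher, 12 of 22 and 15 over the list alone (Csf1r 0.62 ± 0.05; adjusted p = 1.54e-09, and adjusted p = 0.109 with an estimated correlation), as were reactive astrocyte genes, 10 of 20 and 11 over the list alone (adjusted p = 2.03e-08, and adjusted p = 0.109 with an estimated correlation). Interferon and MHC class I genes were higher at 5 of 23, or 10 over the list alone (H2-D1 0.48 ± 0.11). The interferon list gave adjusted p = 5.04e-06, and adjusted p = 0.307 with an estimated correlation. Myelin genes were higher, 11 of 16 by either adjustment (Mag 0.47 ± 0.07; adjusted p = 3.8e-09, and adjusted p = 0.123 with an estimated correlation), as were cholesterol synthesis genes, 12 of 20 and 16 over the list alone (Sqle 0.46 ± 0.06). The cholesterol list gave adjusted p = 1.54e-09, and adjusted p = 0.183 with an estimated correlation. Neuronal and synaptic genes were lower, 11 of 20 and 13 over the list alone (Gad2 -0.38 ± 0.08). The neuronal list gave adjusted p = 1.91e-07, and adjusted p = 0.248 with an estimated correlation. Among markers of other tissue in the sample, Schwann cell genes had a median of 0.651 (1 of 12 called, adjusted p = 0.0507), adipocyte genes of 0.508 (2 of 6, adjusted p = 0.153), skeletal muscle genes of -0.385 (0 of 12, adjusted p = 0.597) and blood cell genes of 0.0378 (0 of 8, adjusted p = 0.94). Genes of meningeal fibroblasts had a median of 0.446 (3 of 11 called; adjusted p = 0.039, and adjusted p = 0.498 with an estimated correlation).

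Treated KO and WT cord differed at 2654 genes, 1395 up and 1259 down, 111 over 2-fold, or 1127 up and 1606 down after a median shift. Libraries did not overlap at 30.2% of the tested genes against 10% by chance. The count was 1681 with array weights, 531 with the 6 libraries alone and 1462 to 2598 with single libraries left out.

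Treated and untreated KO cord differed at 0 genes with limma (1697 of 15838 at unadjusted p under 0.05) and 2 with edgeR, and libraries did not overlap at 12.3% of the tested genes against 10% by chance. Leaving out single libraries gave 0 to 35 genes, the highest without the treated library of animal 24 (8 up and 27 down), and 20 without that of animal 21 (18 up and 2 down). Of 300 changes of each size in simulated reads for this comparison, 56% of those of 1.5-fold and 78.7% of those of 2-fold were found, so smaller changes could be missed. Of 22 macrophage and microglia genes 6 fell over the list alone (median -0.251; adjusted p = 1.33e-05, and adjusted p = 0.403 with an estimated correlation). Of 21 genes of disease-associated microglia 6 fell over the list alone (median -0.203; adjusted p = 3.32e-05, and adjusted p = 0.389 with an estimated correlation). Myelin genes rose, 9 of 16 over the list alone (median 0.262; adjusted p = 1.38e-09, and adjusted p = 0.312 with an estimated correlation). Schwann cell genes had a median of 0.752, with 0 called over all genes (adjusted p = 0.00104 for the list, and adjusted p = 0.573 with an estimated correlation). Blood cell genes had a median of -0.996 (0 of 8 called, adjusted p = 0.0566) and skeletal muscle genes of 0.687 (0 of 12 called, adjusted p = 0.366). Across the 15 cord libraries the muscle actin Acta1 ran from 8.54 to 362, with 260 in the treated library of animal 24.

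Of the 2061 knockout calls in cord, 1371 (66.5%) were still called in the same direction against WT after treatment, 708 up against 99.9 expected and 663 down against 73.7 expected. These differences share the WT libraries. Treated libraries simulated equal to WT gave 0, which follows from drawing no difference and does not measure what the shared libraries add. The covariance was 0.0796 against 0.0151 simulated, so part of the excess may come from the shared libraries. A median of 88.1% of the knockout change was left. The KO and WT libraries that chose these genes also enter that share, and no simulated share stands beside it. It therefore does not measure how much treatment corrected in cord. With treatment, 0 of the 2061 genes reversed at the threshold, which follows from the 0 genes called between treated and untreated KO cord. The count of reversed genes rose when certain single libraries were left out. Of the 2061, 63.8% had the opposite sign against 63.6% in simulations with no treatment effect (covariance -0.0218 against -0.0158).

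The genes called between KO and WT on B6129 were also scored in the mixed background, as the mean log2 level of the genes that rose minus that of the genes that fell. In quadriceps the score was -0.397 ± 0.14 in KO and -1.71 ± 0.11 in WT (difference 1.31, exact p = 0.1, the smallest possible with 3 and 3 libraries), and -1.72 ± 0.077 in treated KO (-1.32 from untreated KO, exact p = 0.1, and -0.0117 from WT, exact p = 1). In cord it was 0.0909 ± 0.035 in KO and -1.12 ± 0.084 in WT (difference 1.21, exact p = 0.1), and -0.126 ± 0.21 in treated KO (-0.217 from untreated KO, exact p = 0.3, and 0.997 from WT, exact p = 0.1). The difference of treated from untreated KO cord was -0.134 without the treated library of animal 22 and -0.336 without that of animal 24. Of the 158 cord genes that rose on B6129, such as C1qa and Cd68, 96.2% were higher in KO than WT on the mixed background and 18.4% were higher in treated than untreated KO (median -0.188; adjusted p = 2.1e-19, and adjusted p = 0.0557 with an estimated correlation).

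**Figure D5:**
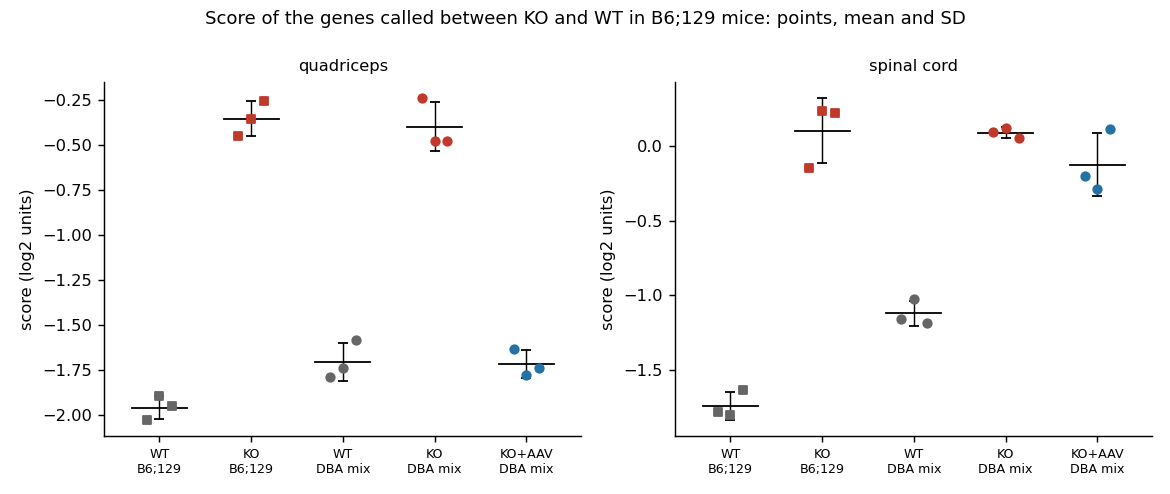
Score of the genes called between KO and WT on B6129 (log2 units) in each library, by group and tissue, with group mean and SD (n = 3); the B6129 groups defined the genes. In the mixed background, treated KO quadriceps average -1.72 beside -1.71 in WT, and treated KO cord -0.126 beside 0.0909 in untreated KO.

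The knockout effect differed between tissues of the same mice. On the mixed background the effect was larger in quadriceps for Mt3 (7.42 ± 0.39, adjusted p = 6.86e-12), for the adhesion molecule Ncam1 of denervated fibres (2.84 ± 0.19, adjusted p = 7.26e-10) and for Chrna1 (2.65 ± 0.27, adjusted p = 1.61e-07). It was lower for Aqp4 (-3.60 ± 0.34, adjusted p = 5.17e-08), for the endothelial genes Flt1 (-1.43 ± 0.27, adjusted p = 0.000241) and Pecam1 (-1.33 ± 0.20, adjusted p = 1.76e-05), and for Ltbp4 (-1.55 ± 0.23, adjusted p = 1.82e-05). On B6129 it was larger for Mt3 (6.82 ± 0.39, adjusted p = 4.32e-11) and lower for Aqp4 (-4.36 ± 0.34, adjusted p = 2.77e-09) and Ltbp4 (-0.70 ± 0.23, adjusted p = 0.0268). The effect on Gaa differed by -0.32 ± 0.18 (adjusted p = 0.185) and -0.37 ± 0.18 (adjusted p = 0.139).

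On the mixed background the tissue difference was higher at 9 of 15 vacuolar ATPase genes and lower at none, or 10 and 1 over the list alone (adjusted p = 0.000508, and adjusted p = 0.394 with an estimated correlation). It was lower at 8 of 10 endothelial genes by either adjustment (adjusted p = 0.00112, and adjusted p = 0.394 with an estimated correlation). All 6 MHC class II genes had a higher effect in quadriceps (adjusted p = 0.00654, and adjusted p = 0.706 with an estimated correlation). In total 4255 of 13187 genes differed on the mixed background (1788 higher, 2467 lower, or 2019 and 1994 after quantile normalization) and 3346 on B6129 (1615 higher, 1731 lower). With animal as a fixed block, pairing the tissues of each mouse, the counts were 4262 and 3343. Called up in both tissues on the mixed background were 311 genes against 173 expected, down 245 against 163, and 226 opposite; on B6129 it was 99 against 23.6, 11 against 3.65, and 6. The expected counts assume independent lists, while both tissues come from the same mice, whose deviations correlate (0.109 to 0.354), so part of the excess may come from the shared animals.

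WT mice of the 2 backgrounds, which were also the 2 sample series, differed mainly in cord. In cord Kcna1, a potassium channel gene, was lower on the mixed background (8.32 ± 0.943 against 80.1 ± 6.56, -3.19 ± 0.15, n = 3 each, adjusted p = 3.06e-10), as were Ltbp4 (11.9 ± 1.56 against 28.4 ± 2.48, -1.22 ± 0.11, adjusted p = 2.23e-07) and Gaa (-0.70 ± 0.09, adjusted p = 5.49e-06). Cox4i1, a subunit of cytochrome oxidase, was higher (762 ± 18.2 against 311 ± 5.64, 1.29 ± 0.06, adjusted p = 3.66e-10). Of 25 respiratory chain genes in cord 19 were higher and 3 lower, 20 and 3 over the list alone (adjusted p = 9.88e-05, adjusted p = 0.91 with an estimated correlation and adjusted p = 0.195 after quantile normalization). Preparation of the samples may enter here: mitochondrial genes took 6.99% to 7.7% of cord reads on B6129 and 13.2% to 17.1% on the mixed background, and over all genes the difference fell with transcript length (Spearman -0.573). In quadriceps Fosb was higher on the mixed background (10 ± 1.16 against 0.732 ± 0.0208, 3.09 ± 0.35, adjusted p = 0.000414), while Ltbp4 stood at 72.2 ± 14.6 against 70.7 ± 6.47 (0.01 ± 0.19, adjusted p = 0.979) and Gaa at 213 ± 42.7 against 275 ± 29 (-0.38 ± 0.15, adjusted p = 0.192).

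Of 12 immediate-early genes in WT quadriceps 2 were higher on the mixed background over all genes and 6 over the list alone (adjusted p = 7.75e-07, and adjusted p = 0.598 with an estimated correlation). WT replicate 4 had the highest mean log2 level of these genes, 5.41, with 140 for the stress gene Mt2. Called genes numbered 10585 of 15838 in cord (5123 up, 5462 down) and 363 of 14113 in quadriceps (196 up, 167 down). Libraries did not overlap at 71.6% and 21.9% of the tested genes, against 10% by chance. The balance depends on the setting: in cord it was 5490 up and 5029 down after a median shift and 5057 and 3669 with a trend in length and GC content removed, and in quadriceps 245 and 247 with array weights. In quadriceps the count was 156 with the 6 libraries alone and 187 to 596 with single libraries left out.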

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

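Each result here was flagged by a test of a difference between groups. The difference of the knockout effect between backgrounds called 40 genes in quadriceps and 83 in cord, and the difference between tissues 4255 genes on the mixed background and 3346 on B6129. When the libraries were regrouped at random after removing additive effects, the real count was the highest of 100 in each case (real groups counted, so 1 of 100). The highest other counts were 3, 1, 2120 and 981. For the difference between tissues, libraries were moved singly, which breaks the pairing of tissues from the same mouse. The share of 1 of 100 is therefore not a measure of chance there.

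In quadriceps the lists whose knockout effect differed between backgrounds were, as median log2 differences, respiration 0.0834, muscle regeneration -0.286, slow fibre 0.897, macrophage -0.485, disease-associated microglia -0.366, interferon and MHC class I 0.314, immediate-early -1.07, Schwann cell 0.408 and adipocyte 0.49. All had adjusted p = 0.958 with an estimated correlation. In cord they were cholesterol synthesis 0.232, disease-associated microglia -0.257, interferon and MHC class I 0.546 and endothelial 0.442, with adjusted p of 0.726 or more with an estimated correlation.

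For comparisons of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split gave the highest count in 1 of 10 for 9 of the comparisons, with real and highest other counts of 5046 and 0, 5562 and 0, 5736 and 17, 421 and 8 and 363 and 18 in quadriceps (KO on B6129, KO on the mixed background, treatment, treated against WT, WT against WT), and 183 and 1, 2061 and 1, 2654 and 14 and 10585 and 1 in cord (KO on B6129, KO on the mixed background, treated against WT, WT against WT). Treated against untreated KO cord gave 0 for the real split and 11 for the highest other; any of the 10 splits gives at least 0, so this comparison says nothing about chance.

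The 10585 genes that differ between WT cords of the 2 backgrounds, against 363 in quadriceps, were weighed after the counts were seen. In cord the log2 difference fell with transcript length (Spearman -0.573, against -0.132 in quadriceps). Removing a trend with length and GC content from each library gave 8726 called genes, of which 7124 were among the 10585. Leaving out mitochondrial genes while shifting each library to one median gave 10495, of which 10113 were among the 10585. Neither accounts for the whole number, though many of the original calls were lost with the trend removed. A difference in RNA or library preparation between the 2 series of cord samples stays possible: differences in cord and quadriceps correlate at r = 0.359, but background could also act differently by tissue. Of the 246 genes called in both tissues 84.6% went the same way (112 up against 56.4 expected of independent lists, 96 down against 55.4), as an effect of background in both tissues would give, though the tissues share their mice and series. The data cannot separate these, because background and series are the same split.

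The 421 genes that differ between treated KO and WT quadriceps crowd near Gaa on chromosome 11 (20 of 322 tested against 9.61 expected, Fisher p = 0.0022 over genes) and on chromosome 4 (41 of 862 against 25.7, p = 0.0035). These regions were chosen after the result was seen. DNA linked to the knocked-out allele, or background DNA that differs between the groups, may account for a part. Of the called genes near Gaa that were measured in cord, 13 of 17 (76.5%) had the same sign in untreated KO against WT cord. On chromosome 4 it was 31 of 39 (79.5%), and among the called genes elsewhere 223 of 340 (65.6%). In the other comparisons on the mixed background the chromosome 4 share was also above that elsewhere, while the share near Gaa went both ways. The shares near Gaa, on chromosome 4 and elsewhere were 64.7%, 87.2% and 71.5% in treated KO against WT cord, and 75%, 63.4% and 57.8% in untreated KO quadriceps on the mixed background, which shares the WT libraries. On B6129 they were 30%, 26.8% and 47.2% in KO quadriceps and 58.8%, 30.8% and 40.9% in KO cord. DNA from DBA2/J is not part of that background's name, so low shares on B6129 do not weigh against background DNA from DBA2/J. The knocked-out allele is present on B6129 too. Near Gaa the B6129 share was below that elsewhere in quadriceps and above it in cord, so these shares do not decide on linked DNA. The explanation stays open. WT replicate 4 of the mixed background stands apart in quadriceps, and without it 227 genes were called, but 124 and 212 were called without the treated libraries of animals 22 and 24, so the fall is not particular to it.

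That treatment changed 0 genes in KO cord was weighed after the count was seen. The same number of libraries called 2061 genes between untreated KO and WT cord, so a change as large and as wide as the knockout effect would have been seen. Skeletal muscle or nerve RNA in 2 cord libraries could raise the spread, and without those 2 libraries 33 genes were called, 8 up and 25 down. WT replicate 3, 1 of the 2, enters only the shared variance, and without the treated library of animal 24 alone 35 genes were called, 32 of them among the 33. Without the treated library of animal 21 instead, 20 genes were called, 18 up and 2 down, so the balance depends on which library is left out. Among the 33, named here only after the values were seen, the microglial genes Trem2 (-0.789), Tyrobp (-0.783), Mpeg1 (-1.07) and the protease Ctsd (-0.472) were lower with treatment. A partial effect of treatment in cord is neither shown nor excluded.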

How the results depend on the processing

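Not every change could be seen: in simulated data 56% of 1.5-fold changes were found in cord and 29.7% in quadriceps. How depth and group size affect this was not tested. Of 11379 values for named called genes under other settings, 10852 stayed called in the same direction, 514 lost the call and 13 reversed; with single libraries left out 6740 of 7536 stayed. A few genes withheld from the text are not counted here. Fewer libraries lower the power of a fit, yet some counts rose with fewer libraries. Counts moved by over 1.5 times for the following, and the cause was not tested.

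Treated KO against WT quadriceps (421 genes) gave 275 without the eBayes trend, 17 with only the groups compared and 124 to 448 with single libraries left out. The difference between backgrounds in quadriceps (40) gave 105 with array weights, 10 with edgeR and 11 to 116 with single libraries left out. WT quadriceps of the 2 backgrounds (363) gave 156 with only the groups compared and 187 to 596 with single libraries left out. KO against WT cord on B6129 (183) gave 654 with array weights, 297 with only the groups compared and 101 to 145 with single libraries left out. On the mixed background (2061) it gave 1365, 570 and 918 to 1892. Treated against untreated KO cord (0) gave 3 with a larger pseudocount, 4 with a higher filter, 5 with robust eBayes, 2 with edgeR, 33 without the 2 libraries with most muscle and nerve RNA, and 0 to 35 with single libraries left out. Treated KO against WT cord (2654) gave 1681 with array weights, 531 with only the groups compared and 1462 to 2598 with single libraries left out. The difference between backgrounds in cord (83) gave 139 with array weights, 146 with only the groups compared, 135 without those 2 libraries and 43 to 95 with single libraries left out. Reversed genes in cord (0) were 1 with a larger pseudocount, 1 with a higher filter, 1 with robust eBayes, 22 without those 2 libraries and 0 to 25 with single libraries left out.

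For the difference between tissues, which pairs tissues by animal, a fixed block for the animal gave 4262 genes and a random one 4520 on the mixed background (4255 without a block), and 3343 and 3624 on B6129 (3346 without a block).

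The score moved with a larger pseudocount and with the 200 genes of smallest p. In quadriceps the difference of KO from WT (1.31) became 1.09 and 3.52, and that of treated from untreated KO (-1.32) became -1.1 and -3.44. In cord KO minus WT (1.21) became 0.927 and 1.13, and 1.03 after quantile normalization, and treated KO minus WT (0.997) became 0.742 with the larger pseudocount. Treated minus untreated KO cord (-0.217) became -0.134 without the treated library of animal 22 and -0.336 without that of animal 24.

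Gene lists depend most on the correlation assumed within a list. With an estimated correlation 6 of 157 list calls remained: 1 in KO quadriceps and 5 in KO cord on B6129, and 0 in each other comparison. With fry 0 lists were called for treated KO against WT quadriceps, for the 2 differences between backgrounds, for WT quadriceps and for treated against untreated KO cord, and 16 for WT cord. After quantile normalization 1 was called for WT cord and 8 for the tissue difference on B6129. Under that normalization some lists changed direction, with adjusted p = 0.759 (glycolysis) and 0.289 (fast fibre) in KO quadriceps on B6129, 0.915 (fast fibre) on the mixed background, 0.849 (fast fibre) with treatment, and 0.729 (respiration) in the tissue difference on B6129. For lists of the tissue difference, all 30 libraries of both tissues were quantile normalized together. The gene counts of the tissue difference after quantile normalization came from normalizing within each tissue.

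Single genes that changed sign, in log2: under quantile normalization Tnnc2 (0.0901) and Tnni2 (0.058) in KO quadriceps on B6129, Acta1 (-0.126) in treated quadriceps, and Mobp (-0.187) in WT cord. Ltbp4 was not called and lay near 0 in WT quadriceps (-0.013 under quantile normalization, -0.131 to 0.161 without single libraries), in KO cord on B6129 (-0.0948 to 0.0227 without single libraries) and in treated against untreated KO cord (-0.00041 under quantile normalization, -0.00816 with edgeR, -0.0992 to 0.145 without single libraries). With the trend in length and GC content removed from WT cord, the signs changed for Stat3 (0.133), Ltbp3 (0.0169), Tyrobp (-0.0871), Etfa (-0.0137), C1qa (-0.052), Ncam1 (0.266), Kcnc1 (0.2), Slc4a4 (0.239) and Ly6a (-0.0487). The cause of these sign changes was not tested beyond the construction of each setting.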

Other observations

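Some other gene groups were left out of the account above. In KO quadriceps on B6129 respiratory chain genes fell, 11 of 25 over all genes and 12 over the list alone (median -0.255, or -0.0295 under quantile normalization; adjusted p = 0.00172, and adjusted p = 0.639 with an estimated correlation), and fatty acid oxidation genes fell, 5 of 20 by either adjustment (median -0.277; adjusted p = 0.00851, and adjusted p = 0.66 with an estimated correlation). Glycolysis genes fell, 8 of 23 with 2 up by either adjustment (median -0.216; adjusted p = 0.0486, and adjusted p = 0.639 with an estimated correlation), but under quantile normalization the list pointed up (median 0.0693, adjusted p = 0.759). Hk1, the hexokinase of most non-muscle cells, rose from 8.93 ± 0.28 to 33.5 ± 5.5 (1.84 ± 0.16, n = 3 each, adjusted p = 2.35e-06). Immediate-early genes rose, 7 of 12 over all genes and 8 over the list alone (Egr1 8.44 ± 5.39 to 74.2 ± 11.8, 3.22 ± 0.49, adjusted p = 0.000224; adjusted p = 0.00249 for the list, and adjusted p = 0.434 with an estimated correlation). The rise of immediate-early genes was not as clear on the mixed background. Their mean log2 level was 4.46 to 4.78 in KO quadriceps and 3.83 to 5.41 in WT quadriceps there. Fosb was lower in KO there (1.59 to 2.66 against 8.71 to 10.8). On B6129 autophagy genes, with 5 up and 4 down of 26, gave adjusted p = 0.421.

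In treated against untreated KO cord, interferon and MHC class I genes had a median of -0.258 with 1 of 23 down over the list alone (adjusted p = 1.55e-05, and adjusted p = 0.508 with an estimated correlation), and genes of meningeal fibroblasts a median of 0.693 (adjusted p = 0.0109, and adjusted p = 0.566 with an estimated correlation). Among single libraries, cord WT replicate 3 of the mixed background had Acta1 at 362, cord KO replicate 2 on B6129 had the sensory ganglion gene Avil at 4.64, and cord treated replicate 22 had the liver gene Alb at 12.9.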
